A study of Paraescarpia echinospica with 7 samples.

How the data were processed

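Single-cell RNA sequencing was done on plume tissue of adult Paraescarpia echinospica. Per the labels' protocols, minced plume was digested with a bacterial protease and EDTA in the cold, strained and made into droplet libraries on polyA RNA with the DNBelab C Series kit. The submitters' processing notes name FastQC and Seurat without versions. The aligner, the genome build and the counting method are not given in the sources used here, nor whether counts are molecules or reads. The authors deposited whole-number counts per gene and cell, not normalized, with no header naming the unit. Each cell in the table had over 200 genes and at least 2036 counts, so low cells had been removed before deposit. The deposited table names genes by reference gene models and by long-read gene models, and 2069 of its 16542 genes are of the second kind. The authors also deposited 3 files of positions: 22994 long-read transcripts of 9844 genes, compared with reference models, a set of long noncoding transcripts, and alternative splicing events. How noncoding transcripts and events were called is not stated in them.

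The 7 samples carry the same labels and form 1 group. The first part of each cell name gives 7 sets, A to G, that match no sample title. A was SY530.GC03.PL.1, B SY530.GC03.PL.3, C SY530.GC03.PL.cDNA.2.J, D SY530.GC03.PL.cDNA.4.J, E SY530.GC04.PL.1, F SY530.GC04.PL.cDNA.2.J and G SY530.GC04.PL.cDNA.3.J. The table was treated as 1 pooled sample. The tests planned across libraries (edgeR's quasi-likelihood test and limma's camera) were not run, as the design fixed before the data were examined provides for this case, and folds and counting intervals are given in their place. Intervals are exact binomial for shares and exact Poisson for counts, at 95%. Where a share was 0, the limit is 3 counts of the total.

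Counts were scaled to 10000 per cell and log-transformed after adding 1. The 2000 most variable genes, ranked within sets, were scaled with values limited to 10 and reduced to 30 principal components. A graph of 15 neighbours was divided by the Leiden method at resolution 0.5 and seed 0 (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Python 3.11.15, matplotlib 3.10.9). The design asked for gene means to be centred per library where cell names map to libraries. They do not, so the main clusters were made without centring, and the centred clusters are an alternative. Clusterings with and without centring had both been looked at before this reading was settled. Scrublet, run per set with an expected rate of 6%, called 77 cells doublets (0.720%). They were kept, and an alternative left them out. Clusters under 20 cells were not described.

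For each described cluster, counts were summed and given as CPM (per 1000000 counts), and the fold against the sum of all other cells was taken with 1 CPM added to both. Genes needed a count in at least 20% of the cluster's cells. The genes named are, by a rule fixed in advance, those with the highest fold in each cluster, limited to 2 identifiers because nothing names the genes, then the genes with the most counts and the noncoding genes with the most counts and with the highest tau among those with at least 500 counts. ONT.5322, ranked after the 2 specific ones named, also leads cluster 10. The part of the rule on genes higher in every library was not applied. The 13 marker lists were matched on symbols and description words. Tau was computed on log2(CPM + 1) over the described clusters. Lists were compared with 10000 random lists matched in 20 bins of total counts (5 bins for the splicing genes). Profile correlations were across genes with at least 32 CPM in a cluster. The joining of clusters at r of 0.9 was chosen after seeing the data.

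The computations were tested on simulated counts for 16542 genes, with 200 genes changed in each of the 16 described clusters against the other cells. Changes of 3-fold were recovered for 94.0% to 100% of the genes, and changes of 4-fold and 8-fold for 100%. Over the 16 clusters, 28 unchanged genes were called. The clusters were given in this simulation, so the clustering step was not tested. All other genes were unchanged by design, while in the data the share of counts from unanchor4648 (described below) differed between clusters. Its median share per cell ran from 17.5% in cluster 9 to 82.0% in cluster 4. The 28 calls are therefore not an error rate for the genes reported below. Of 200 random lists, as long as the noncoding list, among the 8882 tested for tau, 2.50% passed the upper limit, and 93.0% did after a shift of 0.05 in tau. The neighbour comparison, on 212 opposite-strand pairs among 1960 genes, was above its random range in 2 of 100 simulations without an excess and in 92 of 100 with pairs made alike at a rate of 0.1.

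Alternatives covered the filter on cells, correction between sets, resolution, numbers of variable genes and components, doublets, seeds, each set left out, and the limits on folds, detection and counts. Those on the abundant sequence, the added count, detection, 4-fold, the comparison genes, doublets for the noncoding genes, and which genes count as noncoding were chosen after seeing the data.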

Results

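The plume of the cold-seep tubeworm Paraescarpia echinospica, the feathery organ through which the animal takes up dissolved gases, was dissociated and sequenced as single cells. The labels list 7 plume samples of adults, with the same tissue and the same cell type (hemocytes) for each, so they form 1 group and no comparison between conditions was implied. The deposited count table held 10689 cells and 16542 genes. Its cell names fell into 7 sets by their first part, and no set could be tied to 1 of the 7 samples. The sets are called A to G here. Names of sets A to D carried GC03 in their second field and names of sets E to G carried GC04, and the labels do not say what these mean. All cells were therefore treated as 1 pooled sample. Values per set are given as ranges or as each value, without an SD, and every interval covers counting error only.

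The table summed to 48356082 counts. The sets held between 789 cells (set D) and 2004 cells (set F), with a median of 1512. Total counts per set ranged from 3370673 to 10249231. The median count per cell was 3764 over all cells and lay between 2987 and 4318 in the sets. A median of 766 genes had a count in a cell. With every cell thinned to 2000 counts, which left out 0 cells, the median was 520 genes, from 275 in set D to 591 in set E. Pearson's r of log2 CPM (counts per 1000000) between sets was lowest for sets D and E (0.909) and highest for sets E and G (0.989). It was 0.949 to 0.984 within sets A to D and 0.988 to 0.989 within sets E to G. Between these 2 kinds of sets it was 0.909 to 0.939. The main clusters were made without correction for this split.

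**Figure D1:**
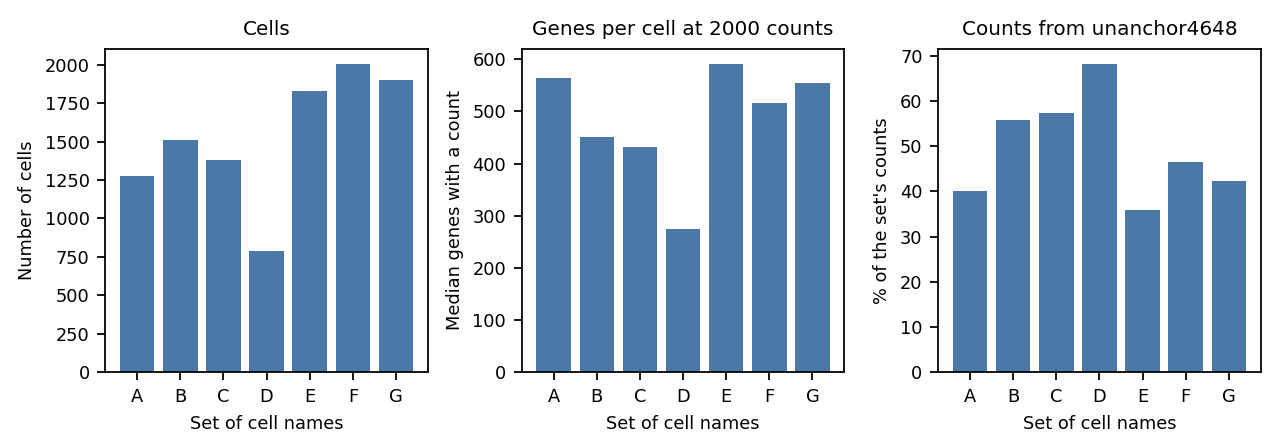
Bars give, for each set of cell names A to G, the number of cells, the median number of genes with a count in cells thinned to 2000 counts, and the percentage of the set's counts that came from the sequence unanchor4648. Set D had the fewest cells (789), the fewest genes per cell (275) and the highest share from that sequence (68.2%).

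A single sequence supplied much of the RNA that was counted. The 12 genes placed on unanchor4648 took 47.8% of all counts, from 35.9% in set E to 68.2% in set D. The gene with the most counts, ONT.9787 (unanchor4648, 14545 to 15528, minus strand, 1 exon), took 35.9% of the counts, between 26.0% and 51.3% in the sets, and had a count in each of the 10689 cells. The next, ONT.9783 on the same sequence (10245 to 11439, minus strand, 1 exon), took 5.56%. Of the 10 most abundant genes, 4 lay on this sequence. Its 19 long-read transcripts ran from base 6678 to base 22480, all on 1 strand, and 0 of them had an intron. Of the transcripts on other sequences, 91.6% were spliced. Positions are those of the deposited long-read models, for a genome build that is not given in the sources used here. Those models placed 7887 of the genes, and genes without a position below were among the rest.

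Which cell populations the plume contains was addressed by clustering. The cells formed 17 clusters, and 16 of them, with at least 20 cells each, are described, numbered by size. The remaining 15 cells are not described. Most cells belonged to 3 groups of clusters with similar profiles, joined where Pearson's r across 4909 genes was at least 0.9 with any cluster of the group (clusters 4 and 12, at 0.87, were linked through cluster 9). Clusters 1, 5, 6, 7 and 8 together held 49.7% of the cells (95% exact binomial interval 48.7 to 50.6%), from 38.7% of set D to 52.8% of set A. Clusters 2 and 3 held 26.2% (25.3 to 27.0%), with 10.3% to 14.3% in sets A to D and 34.5% to 42.0% in sets E to G. Clusters 4, 9 and 12 held 17.5% (16.8 to 18.2%), with 19.4% to 42.0% in sets A to D and 6.68% to 10.1% in sets E to G. The other 6 clusters (10, 11, 13, 14, 15 and 16) were not joined to any other at that limit. Neither the deposited files nor the labels pair the gene identifiers with gene names, so the clusters keep their numbers and 2 identifiers are given for each.

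**Figure D2:**
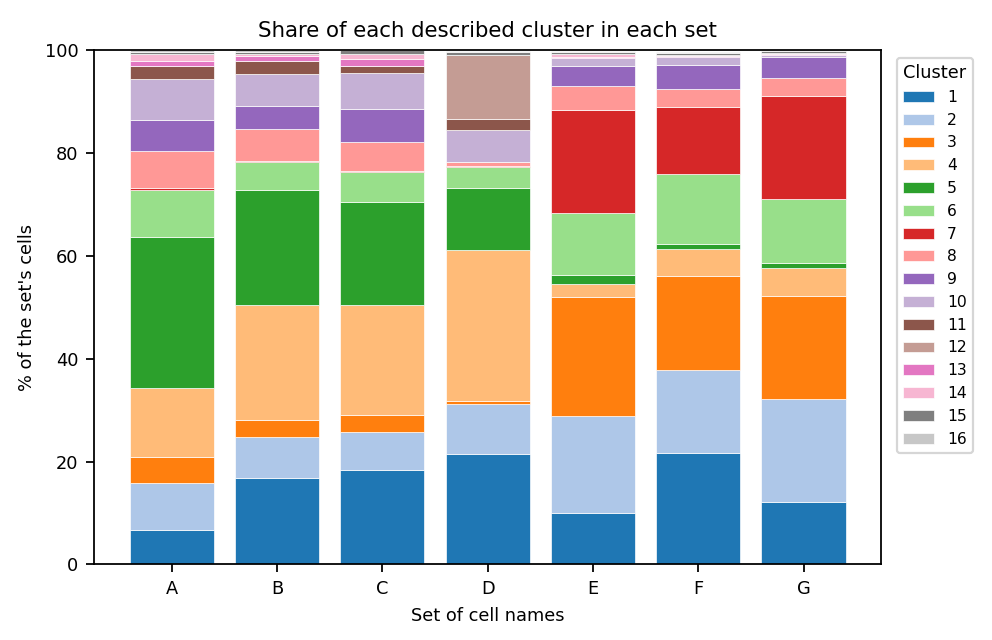
Stacked bars give the percentage of each set's cells in each of the 16 described clusters, for sets A to G. Cluster 5 took 12% to 29.3% of sets A to D, and cluster 7 took 13.1% to 20% of sets E to G. Cluster 12 appeared in set D alone.

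**Figure D3:**
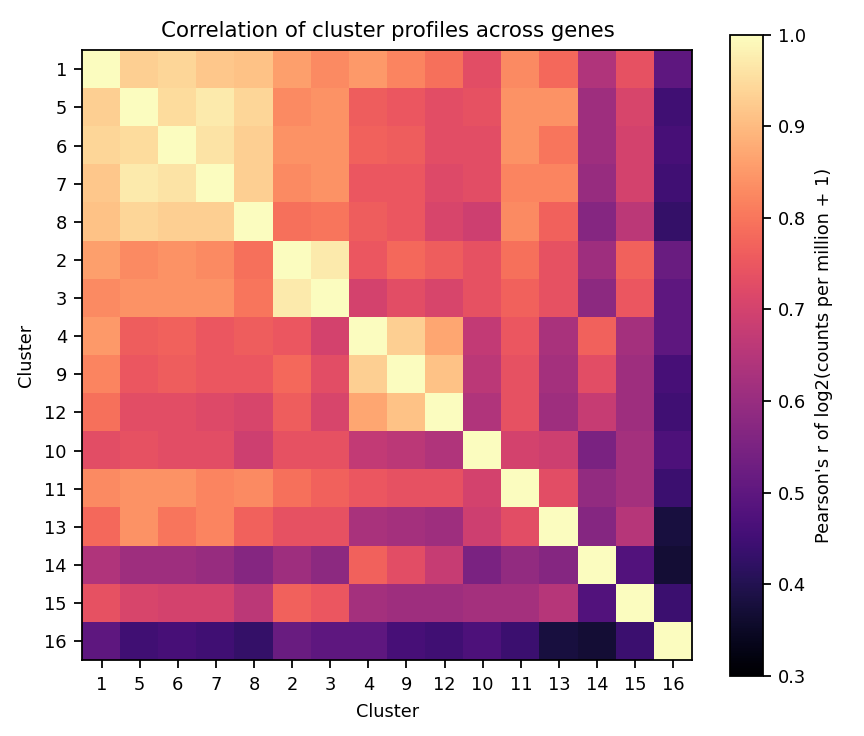
Colour gives Pearson's r between the summed profiles of each pair of clusters, as log2(CPM + 1) across 4909 genes, with both axes in the same order of clusters. The blocks of clusters 1, 5, 6, 7 and 8, of clusters 2 and 3, and of clusters 4, 9 and 12 stand out, and cluster 16 had an r of at most 0.52 with any other.

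Genes that were higher in 1 cluster than in all the other cells gave each population its profile. In total 2334 genes had a count in at least 20% of the cells of a described cluster and at least 2-fold more CPM there than in the other cells, with 1 CPM added to both. They came from 2921 genes that passed the 20% limit in at least 1 cluster. Of the 2334 genes, 1365 (58.5%) were higher in exactly 1 cluster. The number per cluster ran from 1 gene in cluster 1 to 483 genes in cluster 13. The sets could not be tied to samples, so whether they are replicates is unknown and no test was made. The clusters were made from the same counts, and with clusters from 1 random part of the counts and genes from the other part 978 genes passed, 949 of them among the 2334.

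Cluster 10, with 402 cells (3.76%, 3.41 to 4.14%), was set apart most sharply among the larger clusters. Its leading gene was ONT.5322, which the deposited models class as a long noncoding RNA (Superscaffold4, 22920346 to 22927651, plus strand, 5 exons). ONT.5322 reached 8432 CPM (8292 to 8574) in cluster 10 and 42.5 (40.6 to 44.4) in the other cells, a 194-fold difference. It had a count in 392 of the cluster's cells and in 14% of the others, at median depths of 3482 and 3776 counts per cell. PE-Scaf9768-4.16 (Superscaffold13, 13317776 to 13323597, minus strand) was 172-fold higher, at 1677 CPM (1615 to 1741), with counts in 89.1% against 3.42% of the cells, and 90.1-fold with 10 CPM added in place of 1. In all, 404 genes were at least 2-fold higher in cluster 10, 98 of them by at least 10-fold. Both leading genes were higher in each of the 6 sets with at least 20 cells of the cluster. Cluster 10 took 6.21% to 7.83% of sets A to D and 0.421% to 1.42% of sets E to G.

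Clusters 8 and 9 each had strong leading genes in 6 of 6 sets with enough cells. In cluster 8 (488 cells), PE-Scaf7346-4.1 was 48.6-fold higher at 2451 CPM (2389 to 2515) and had a count in 93.2% of the cells against 10.8% of the others. PE-Scaf5718-0.24 was 45.4-fold higher at 3653 CPM (3576 to 3730). In cluster 9 (481 cells), PE-Scaf5737-1.4 (Superscaffold9, 50230016 to 50248748, minus strand) was 50.4-fold higher at 1318 CPM (1270 to 1368), with counts in 96.9% against 6.75% of the cells. ONT.5536 (Superscaffold4, 49602355 to 49612113, minus strand) was 47.5-fold higher, and 20.4-fold with 10 CPM added. Cluster 9 had the lowest share of counts from unanchor4648, with a median of 17.5% per cell, and 420 genes at 2-fold or more. With the counts of unanchor4648 left out of the totals, the fold of PE-Scaf5737-1.4 was 32.5.

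Clusters 2 and 3 shared most of the smaller list: 112 of the 131 genes that were 2-fold higher in cluster 2 were also among the 387 of cluster 3. The line between both clusters was not stable: with 5 other seeds the best match of cluster 2 held 6.09% to 9.35% of the cells, against 13.7% here. In cluster 2 (1465 cells), PE-Scaf10212-2.11 (Superscaffold3, 74131775 to 74181972, minus strand) was 25.7-fold higher, at 624 CPM (603 to 644) against 23.3 (21.8 to 24.8), with counts in 60.1% against 7.59% of the cells. PE-Scaf6297-2.3 (Superscaffold5, 3324296 to 3356327, minus strand) was 14.7-fold higher there. In cluster 3 (1332 cells), PE-Scaf11261-1.6 was 25.9-fold higher at 125 CPM (117 to 134), and PE-Scaf8451-3.3 was 25.1-fold higher at 104 CPM (96.6 to 112). These last 2 folds depend on the added count: with 10 CPM added they were 9.74 and 8.66. With unanchor4648 left out of the totals they were 18.3 and 18.1. Cluster 3 took 0.634% to 5.01% of sets A to D and 18.3% to 23.1% of sets E to G, so its folds also mix cluster with set. Within each of the 6 sets with at least 20 cells of cluster 3 both of its genes were higher.

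Clusters 5, 6 and 7 had profiles with r between 0.95 and 0.97. PE-Scaf12500-6.4 (Superscaffold9, 49149209 to 49168989, plus strand) led cluster 7 (1022 cells) at 1544 CPM (1512 to 1578) and was 10.5-fold higher than in the other cells, with counts in 97.3% against 25.7% of the cells. Its next highest level, 567 CPM, was in cluster 5. PE-Scaf2696-17.3 was 8.50-fold higher in cluster 7 (5.66-fold with 10 CPM added). Cluster 7 came mostly from sets E to G and cluster 5 from sets A to D (shares below), so their folds mix cluster with set. Within each of the 3 sets with at least 20 cells of cluster 7 both of its genes were higher. In cluster 5 (1151 cells), ONT.4603 (Superscaffold3, 15812521 to 15899022, minus strand) was 6.04-fold (higher in 5 of 6 sets, and 3.97-fold with 10 CPM added) and PE-Scaf5616-1.1 was 5.64-fold higher. In cluster 6 (1045 cells), PE-Scaf8483-8.4 (Superscaffold7, 28085938 to 28097064, minus strand) was 8.28-fold and PE-Scaf2054-6.8 (Superscaffold7, 55902788 to 55909394, plus strand) was 8.04-fold higher. PE-Scaf8483-8.4 was at 236 CPM in cluster 6 and at 1005 in cluster 13, and ONT.4603 was at 76.7 in cluster 5 and at 85.9 in cluster 13. Cluster 5 made up 21.9% of the cells of sets A to D and 1.15% of those of sets E to G, while cluster 7 made up 0.282% and 17.6%. Over the 4960 and 5729 cells of these sets, the median depths were 3627 and 3878 counts per cell. Thinned to 2000 counts and clustered anew, clusters 5 and 7 had the same best match. With total counts matched between sets A to D and sets E to G the split stayed. The best match of cluster 5 then took 21% and 1.2% of their cells, and that of cluster 7 took 0.52% and 18%.

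Clusters 1 (1605 cells) and 4 (1292 cells) were dominated by the abundant sequence. Its genes took a median of 80.4% of the counts of a cell in cluster 1 and 82.0% in cluster 4, and 353 and 346 genes had a count in the median cell. The share was also high in clusters 15 (66.7%) and 16 (70.3%). PE-Scaf2882-3.2 was the only gene at 2-fold in cluster 1 (2.37-fold, 90.9 CPM, 83.6 to 98.6), and ONT.9787 followed at 1.92-fold. PE-Scaf2882-3.2 was higher still in cluster 6, at 151 CPM. In cluster 4, PE-Scaf6592-1.5 (Superscaffold6, 2545213 to 2571958, minus strand) was 5.87-fold and PE-Scaf2100-4.3 (Superscaffold1, 43175625 to 43215985, minus strand) was 5.67-fold higher. PE-Scaf2100-4.3 was higher in 5 of the 7 sets. Neither had its highest level in cluster 4: PE-Scaf6592-1.5 reached 757 CPM in cluster 16 and PE-Scaf2100-4.3 reached 539 CPM in cluster 14, against 172 and 248 in cluster 4. With unanchor4648 left out of the totals these 4 folds became 6.64, 5.36, 15.3 and 14.7, in the same order.

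The clusters with the highest folds, 13 and 16, were among the smallest, and for clusters 13 to 16 no set had the 20 cells needed to look at sets apart. In cluster 11 (108 cells), PE-Scaf6813-3.1 (Superscaffold12, 49372682 to 49407370, minus strand) was 126-fold and PE-Scaf7382-1.1 (Superscaffold8, 38397678 to 38400891, plus strand) was 87.9-fold higher, from 107 and 200 counts. Sets E to G held 0 cells of cluster 11 among 5729, which allows a share of up to 0.0524%. Cluster 12 (99 cells) came from set D alone, so cluster and set cannot be separated. PE-Scaf7230-5.8 (Superscaffold6, 44666209 to 44684659, minus strand) was 28.0-fold and ONT.6781 (Superscaffold6, 16455841 to 16534977, plus strand) was 14.5-fold higher in it. PE-Scaf7230-5.8 was higher in cluster 11 (1695 CPM) than in cluster 12 (783), and 168 of its 200 genes at 2-fold were also among those of cluster 9. In cluster 13 (59 cells), PE-Scaf4124-5.3 was 256-fold and PE-Scaf4897-0.7 was 248-fold higher, at 382 CPM (307 to 470) and 468 (384 to 565). In cluster 14 (53 cells), ONT.1214 (Superscaffold10, 29644087 to 29646433, plus strand), also classed as a long noncoding RNA, was 176-fold (23.5% of its counts there from 1 cell) and PE-Scaf6377-0.5 was 115-fold higher. Cluster 14 was not stable: without set A, B or D its best match held 5.05% to 7.03% of the cells, against 0.496% here. With 5 other seeds it held 0.477% to 0.496%. In cluster 15 (52 cells), PE-Scaf1989-0.2 (Superscaffold3, 27300884 to 27311888, minus strand) reached 11109 CPM (10634 to 11599), 116-fold higher. ONT.643 (Superscaffold1, 60890037 to 60902060, minus strand) was 89.0-fold higher there and 54.8-fold without set F. In cluster 16 (20 cells), ONT.2393 (Superscaffold12, 25100708 to 25148323, minus strand) was 407-fold higher, but 1 cell gave 55.8% of its counts and the fold was 55.4 without set A. PE-Scaf9175-8.2 (Superscaffold4, 33941201 to 33998991, minus strand) was 404-fold higher in cluster 16, from 47 counts in 11 cells, with 23.4% of them from 1 cell. Most of these folds depended on the added count. With 10 CPM in place of 1, and in the order named, they were 24 and 33.7 in cluster 11, 37.4 and 43.9 in cluster 13, 43.1 and 32.6 in cluster 14, and 69.5 and 63.9 in cluster 16. ONT.6781 was then at 7.71 and ONT.643 at 20.1, while PE-Scaf7230-5.8 in cluster 12 (21.4) and PE-Scaf1989-0.2 (106) changed less. With 0.1 CPM they were 638 and 471 in cluster 13 and 800 and 880 in cluster 16, with PE-Scaf6813-3.1 at 224 and ONT.643 at 139. With unanchor4648 left out of the totals, the folds of cluster 16 were 815 and 840 and that of ONT.643 was 155.

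**Figure D4:**
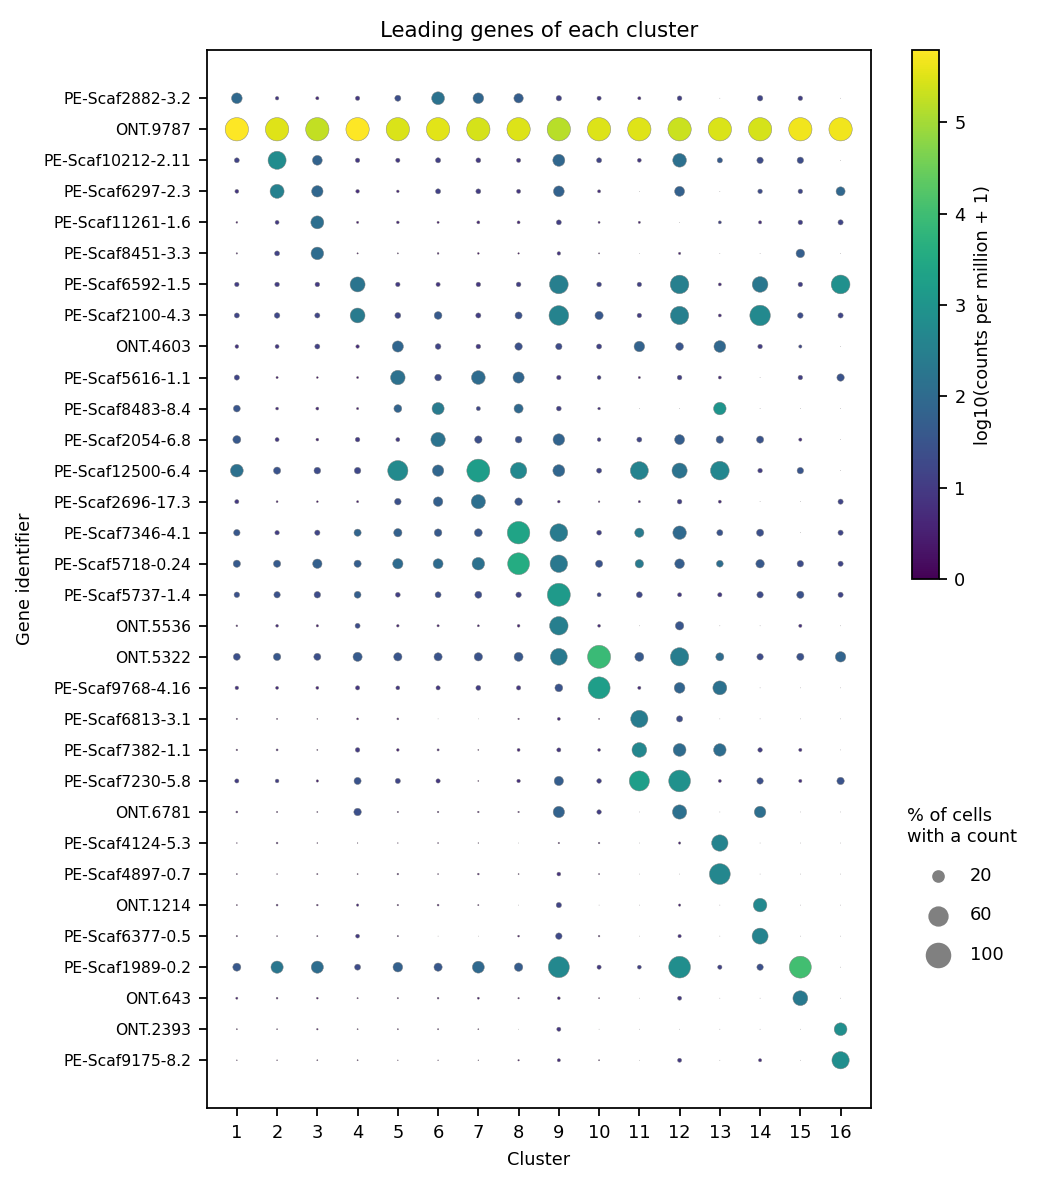
Each dot is 1 gene in 1 cluster: its area gives the percentage of the cluster's cells with a count and its colour the log10 of CPM plus 1. Genes are the 2 leading ones of each cluster, in cluster order, and ONT.9787 was present in every cluster while ONT.5322 reached 8432 CPM in cluster 10.

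The 13 lists of marker genes fixed in advance, for hemoglobin, cilia, muscle, neurons, epithelium, gas transport, sulfide metabolism, immune cells, proliferation, stress, ribosomes, oxidative phosphorylation and peptidases, could not be read out. They name genes by symbol or description, and 0 of the 16542 identifiers matched.

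Long noncoding RNA models were compared with other genes for abundance and cluster specificity. The authors' models held 497 transcripts of 367 genes, with a median length of 721 bases and 2 exons, against 1732 bases and 6 exons for the other long-read transcripts. Of these genes 291 were in the count table, and they took 0.959% of all counts, or 1.84% with unanchor4648 left out. For 157 of them every long-read transcript was in the noncoding models, so counts of the others, among them ONT.7391, ONT.4669 and ONT.5349 below, can include other transcripts. The gene with the most counts was ONT.7391 (Superscaffold7, 200884 to 224267, minus strand), with 93900 counts and a count in 96.8% of the cells. ONT.4669 (Superscaffold3, 25345616 to 25364625, plus strand) followed with 76090. The most cluster-specific of those with at least 500 counts were ONT.5349 (Superscaffold4, 26337797 to 26392283, plus strand; 66.2 CPM in cluster 10, 54.3 to 80) and ONT.7692 (Superscaffold7, 23886594 to 23897077, plus strand; 97.8 in cluster 6, 89.3 to 107). Over the noncoding genes with at least 50 counts, the median specificity index tau, which is 0 for even expression and 1 for expression in a single cluster, was 0.544. Random lists matched on expression had a mean median of 0.506 (95% of lists 0.475 to 0.539), which put the noncoding genes at percentile 98.90. This depended on the settings. For genes with few counts, tau can turn on single counts in the smallest clusters, since 1 count in cluster 16 is 14.3 CPM. The percentile stayed at 98.31 at resolution 1.0 and at 98.81 without called doublets, and was 99.96 against other long-read genes alone. With at least 100 counts (145 genes) it was 13.03, and with at least 10 it was 60.24. It was 63.02 with unanchor4648 left out of the totals and 58.75 for the genes with noncoding transcripts alone. It was 65.61 to 97.15 with any 1 set left out. The share of cells with a count (percentile 15.62) and the highest fold in a cluster (percentile 28.20) were not above those of the random lists.

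Alternative splicing was described from the authors' deposited event file, which has no samples of its own. It held 2351 events in 1384 genes. Skipped exons were the most frequent type, with 800 events (34.0%, exact binomial interval 32.1 to 36.0%) in 633 genes. Alternative donors made up 354 events (15.1%, 13.6 to 16.6%), retained introns 299 (12.7%, 11.4 to 14.1%), alternative acceptors 269 (11.4%, 10.2 to 12.8%) and mutually exclusive exons 135 (5.74%, 4.84 to 6.76%). The remaining 494 events (21.0%) were of other types, whose structures were not looked at. A single event was listed for 1010 of the genes (73.0%), and the highest number in 1 gene was 51. Genes with events had a median tau of 0.279, against 0.281 (0.276 to 0.288) for random lists of other genes with several transcripts, matched on expression (percentile 22.29). Without that matching, 39.6% of the genes with events were at 2-fold in a cluster against 29.3% of the others, at median counts of 1051 and 755.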

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

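Whether clusters 9 and 12 fall together under other settings was looked at only after the result was seen.

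Across the 7 sets, 23 measures (cells, depth, shares of counts, the number in the cell names and cluster shares) were searched for a set that lay far from the others by Dixon's criterion (0.568 for 7 values). Chance flags about 1 in 20 groups of independent values from 1 normal population. The sets fall into 2 kinds and the clusters were made without correction for sets, so that rate need not hold here. Of the 23 measures, 2 stood out. Both concern set D, and shares that sum to a fixed total are not independent of each other. Cluster 12 took 12.5% of the cells of set D and 0 of the 9900 cells of the other sets. Cluster 9 took 0 of the 789 cells of set D, which allows a share of up to 0.380%, and 4.00% to 6.30% of each other set. The absence of cluster 9 from set D depends on how clusters 9 and 12 are divided. In 3 of 23 other settings (ComBat, 15 principal components and split counts) both had 1 best match. That match took 12.2% to 12.5% of set D and 4.00% to 6.30% of each other set, so set D then had the highest share. In the other settings their best matches differed. Of the 200 genes at least 2-fold higher in cluster 12, 168 were also at least 2-fold higher in cluster 9. The leading genes differed: PE-Scaf5737-1.4 was at 1318 CPM in cluster 9 and 8.02 in cluster 12, and ONT.5536 at 305 and 34.8. PE-Scaf7230-5.8 was at 49.3 CPM in cluster 9 and 783 in cluster 12, and ONT.6781 at 64.5 and 128.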

How the results depend on the processing

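The number of described clusters was 16 and lay between 11 (split counts) and 23 (resolution 1.0) elsewhere, and which cells were grouped varied. The adjusted Rand index with the main clusters was 0.68 to 0.83 over 5 other seeds, 0.58 to 0.74 with a set left out and 0.55 to 0.90 under the 12 others. Clusters 6, 8, 9, 10, 11 and 13 had a match with a Jaccard index of at least 0.5 under each of the 24 settings. Cluster 2 had one under 8 and cluster 14 under 12. Clusters 4 and 7 had one under 17, clusters 1, 5 and 15 under 18, cluster 16 under 19 and cluster 3 under 23. Cluster 12, compared under 23, had one under 20. The lowest index was 0.01 for cluster 15 and 0.03 for cluster 16. Centring per set gave 17 described clusters and an index of 0.60; it became an alternative after clusterings of both kinds had been seen. Of the shares of cells per cluster, 185 stayed within the counting interval and 182 did not. With seed 3 the best match of cluster 2 held 6.25% of the cells against 13.7%. Clusters 5 and 7 had 1 best match in 8 of the 24, among them ComBat, resolution 0.25 and split counts. With gene means centred per set their best matches differed and held 11.3% and 9.83% of the cells. The median of 520 genes per cell at 2000 counts was 766 unthinned and 582 for cells with at least 500 genes. The 2334 genes at 2-fold became 978 with split counts, where depth, clusters (11) and the separation of clustering from gene calling all changed. They became 4395 and 945 with counts required in 10% and 40% of the cells, and 1094 at 4-fold. Leaving unanchor4648 out of the totals gave 1996, with 1930 of them among the 2334. With any fold all 2921 detected genes passed. Leaving out a set gave 2009 to 2217.

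The specificity of noncoding genes depended on the settings. Its percentile of 98.90 became 13.03 (below the mean of the random lists) with at least 100 counts, 60.24 with at least 10 and 58.56 with no minimum. It was 63.02 without unanchor4648 in the totals and 58.75 for the 85 genes with noncoding transcripts alone, and 65.61 (without set B) to 97.15 (without set D) with a set left out. The cause was not tested. Counting splicing events at the same place once left 2115.

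DESeq2, filterByExpr, other minimum cells per library, the unblocked fit, camera's alternatives, fry and sign flips were not run, since no sets are tied to samples. No analysis paired within sets was run. No cell was removed by the filter of 200 genes, so leaving out the filter gives the same cells.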

Other observations

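Tests of clusters 1 and 4, and for clusters 5 and 7 the test at matched depth and the count of settings in which they merge, were chosen after the result was seen, and the other tests were set before it.

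Genes that lie next to each other tended to lead the same cluster. Among 472 adjacent pairs of the 1960 placed genes at 2-fold, 98 pairs (a share of 0.208) had their highest fold in the same cluster, against a mean of 0.110 (95% of permutations 0.083 to 0.138) when clusters were permuted over genes. Overlapping pairs shared it most (13 of 27), where reads of 1 model can be counted for another. Overlapping or fragmented models do not account for all of it, as far as the long-read positions of the 7887 placed genes show. Opposite-strand pairs that do not overlap by these positions had a share of 0.193, above their permuted range of 0.071 to 0.151. Pairs over 10 kb apart had a share of 0.179. A shared local control of neighbouring genes, or duplicated genes, is a candidate explanation that was not tested.

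Clusters 5 and 7 had almost opposite shares in sets A to D and sets E to G. The test set in advance, thinning all cells to 2000 counts, came out as a difference in counts per cell would have it: the best match of cluster 7 had a share in sets A to D that was 1.1 times that in sets E to G, where a value below 0.333 would have spoken against depth. That test was a poor one, because clusters 5 and 7 then had the same best match, as they did under 7 settings that kept all counts. With total counts per cell matched between the 2 kinds of sets the ratio was 0.029. That argues against a difference in total counts between the sets, and rests on a test added once the first result was known. The matching changed little, since the medians were 3627 and 3878 before it. Counts outside unanchor4648 were not matched apart from the total, so depth in the other genes was not tested. The median cell had 3682 counts in cluster 5 and 4588 in cluster 7. A shift that all cells share stays open. Across the 110 genes that differed at least 2-fold between clusters 7 and 5, that log2 ratio followed the log2 ratio between the 2 kinds of sets inside clusters 2, 8 and 10 as well (Pearson's r of 0.77, 0.93 and 0.54, across genes, which are not replicates). Rank correlations were lower, at 0.47, 0.84 and 0.37, and 85.5%, 98.2% and 71.8% of the genes went the same way. In cluster 10 sets E to G gave 62 cells. For genes higher in cluster 7, the median log2 ratio of sets E to G over A to D was 0.76, 1.11 and 0.97. Between clusters 7 and 5 it was 1.23. For genes higher in cluster 5 these medians were -0.90, -1.42 and -0.76, against -1.63. The limit of 0.5 was thus passed in all 3 clusters by Pearson's r and in cluster 8 alone by rank. ComBat over sets gave clusters 5 and 7 the same best match, and centring gene means per set did not. The 2 clusters may be 1 cell population seen in 2 kinds of sets, which this leaves open. Whether animals, preparation or free RNA differ between them is not given.

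Clusters 1 and 4 had few genes per cell and most of their counts from unanchor4648, as did the small clusters 15 and 16 for their counts. Their median count per cell was 0.954 times that of the other cells, all counts included. The lowest count of a deposited cell was 2036 in set A and 3049 in set F, against medians of 2987 and 4318. Cells with far fewer counts are thus absent from the table, so this ratio cannot decide whether fewer counts per cell play a part. Without the sequence, medians of 707 and 734 counts were left per cell in clusters 1 and 4 against 2445 in the other cells, so counts of other genes were fewer. A candidate explanation for the sequence itself is a mitochondrial genome: of its 19 long-read models 0 had 2 or more exons and all lay on 1 strand, while each of the 17 other sequences with at least 5 genes had an intron or both strands. A loss of other RNA, from cells of all types alike, stays open for both. Without that sequence 46 genes were at 2-fold in cluster 4 (32 of them also in cluster 9). In cluster 1 there were 18 (5 of them also in cluster 6). But the clusters were made from the same genes, so cells that lost RNA would still be sorted by what was left.

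The number after N at the end of each cell name went with depth. The 9457 cells with 1 had a median of 3571 counts, the 1112 cells with 2 had 7322 (2.05 times as many), and the 109 cells with 3 had 10637 (2.98 times). Cells with a number above 1 made up 5.04% of set F and 10.5% to 14.7% of the other sets, and 20.4% (18.3 to 22.7%) of cluster 4 against 6.85% (5.67 to 8.20%) of cluster 1.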
